A study of Botrytis cinerea and Vitis vinifera
Botrytis cinerea and Vitis vinifera with 9 samples.

How the data were processed

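Gene-level read counts were taken for 9 RNA sequencing libraries in 3 groups of 3 replicates: Botrytis cinerea mycelium grown in vitro, grape berries injected with conidia of the fungus, and control berries injected with sterile water. Group and replicate followed the sample titles, and every column of the tables was matched to a library. The libraries were unstranded TruSeq v2 libraries made from 2.5 µg of RNA and sequenced on a NextSeq 500, so antisense transcripts and overlapping genes were not separable. How reads shared between paralogs were assigned is not given in the sources used here.

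The authors deposited 2 count tables, in which each value is a count of raw reads per gene. The table of grape genes lists 29970 and that of Botrytis lists 11702, each for all 9 libraries. The authors also deposited 2 tables of normalized signal for the genes they tested, 22253 of grape and 10881 of Botrytis, which their file names describe as counts normalized with edgeR; the exact method is not given in the sources used here. The submitters' processing notes name TopHat2 2.0.11, TopHat, HTSeq and edgeR, without stating the step each served. The genome builds are not given in the sources used here. All values reported here were computed from the raw counts. Across genes, the log2 fold changes of the deposited signal and of the raw counts correlated at r = 0.999 for grape and 0.921 for Botrytis, with genes not being independent replicates. The deposited signal lies above 0 for 4953 of 6726 raw zeros of Botrytis genes and 255 of 556 raw zeros of grape genes, and it was used for no fold change.

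Botrytis gene IDs were paired with symbols through the RefSeq gene table of the assembly ASM14353v4, which held 11688 of the 11702 IDs and gave a symbol for 2626. The other 14 IDs stayed in the fit without a name. No table at hand named the grape IDs, so the grape gene lists planned for stilbene synthesis, pathogenesis-related proteins, hormones and other functions could not be formed and were not tested.

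The groups, the tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Grape genes were compared between infected and control berries, and Botrytis genes between infected berries and mycelium in vitro. Each comparison used the 6 libraries concerned and the genes of that organism alone, with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (minimum count 10, minimum total 15), libraries were scaled by TMM factors, and the quasi-likelihood F test (two-sided) was followed by Benjamini-Hochberg adjustment. A gene was called changed at an adjusted p under 0.05. Fold changes used the default prior count of the edgeR fit, and a prior count of 2 entered values on the log2 CPM scale only. The SE of a log2 fold change is its absolute value over the square root of the F statistic. It restates the test and is no separate measure of spread. CPM are the counts of a gene relative to the library total of that organism, in the usual unit of edgeR. They were scaled by the same factors and are given as mean ± SD with n = 3. The berry replicates are not stated to come from separate batches, so p-values measure the spread between these libraries only.

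The share of fungal counts was the Botrytis counts over the counts on genes of both organisms, with a 95% exact Clopper-Pearson interval per library. Intervals and floors cover counting error only. A gene at 0 in a group was set against a floor of 3 counts over that group, which gives the folds written as at least. The low ends of the 95% exact intervals are smaller, such as 5.75 against 7.08 for Bcstc4 and 1.34 against 1.66 for Bcdmats2. For genes with 1 to 3 counts the ratio is given with its exact counting interval.

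The 23 Botrytis gene lists cover the botrydial cluster, the botcinic acid cluster, pectin degradation, degradation of cellulose, hemicellulose and cutin, secreted inducers of cell death, proteases, laccases, reactive oxygen production and removal, polyketide and peptide synthases with terpene cyclases, melanin synthesis, transporters, sugar transport and use, regulators of light, clock and development, signalling kinases and G proteins, chitin and glucan synthases with hydrophobins, ergosterol synthesis, cytosolic ribosomal proteins, respiration and the citrate cycle, the glyoxylate cycle with fatty acid oxidation, the proteasome, heat shock proteins, histones and replication, and reference genes. They were formed by patterns on gene symbols. Lists of at least 3 tested genes were tested with camera of limma 3.58.1 on log2 CPM with a preset correlation of 0.01 between genes, adjusted over the 22 lists tested. The same test with a correlation estimated per list, and fry, were run as alternatives. Fry asks whether a list's genes move on balance in a single direction, without comparing them with other genes. Camera compares a list with the other genes on log2 CPM, where each library weighs equally, so its directions are relative to those genes.

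Named Botrytis genes were, among genes with a symbol whose groups did not overlap in CPM and with at least 50 counts in every library of the higher group, the 10 with the largest rise and the 10 with the largest fall. From each list the called member with the highest mean CPM and the called member with the largest fold change were added, and all members of lists of up to 7 tested genes. For grape the 2 IDs with the largest rise and the 2 with the largest fall were taken by the same filters. Of Botrytis genes with a symbol, 16 passed these filters upward and 386 downward, and of all grape genes 4424 and 4952. For Botrytis rises the minimum of 50 counts had to be met in infected replicate 2, which held 51380 Botrytis counts. For falls it applied to the deep in vitro libraries only, so the numbers of Botrytis rises and falls cannot be compared.

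The alternatives were DESeq2 1.42.0, DESeq2 size factors, upper-quartile factors or library totals in place of TMM, no count filter, the genes the authors tested, at least 50 counts in every library of a group, limma-trend, the replicate number as a block, stricter thresholds, thinning to the smallest Botrytis total, and leaving out each library in turn. Subtracting the mean count of the control berries, and recounting each list without infected replicate 2, were added after the data had been seen.

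The pipeline was tested on simulated data built from these libraries, over 5 draws of 100 changed genes at each size. In grape 77% of genes changed 2-fold and 95.4% of those changed 4-fold were recovered, and 81 of 1013 calls (8%) were false. In Botrytis 26.4% and 77.4% were recovered, and 55 of 607 calls (9.06%) were false. These false shares exceed the nominal 5%. Far fewer genes were changed in the simulation than were called in the real data, so neither the recovered nor the false shares need hold for the real calls.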

Results

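Noble rot is a slow infection of ripe, drying grapes by the grey mould fungus Botrytis cinerea, and RNA sequencing measured the transcripts of both organisms in it. Mycelium of strain B05.10 was grown for 7 days at 22 °C in potato dextrose broth. Berries of the white cultivar Garganega, at 26.6 °Brix after a weight loss of 30%, received conidia by injection (500 berries) or sterile water (500 berries). They were held at 15 °C for 15 h in darkness and at 18 °C for 9 h in light. Infected berries were taken at the stage named pourri plein. Each of the 3 groups had 3 libraries, and a library held between 32125645 and 52067831 counts on genes of either organism.

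Infected berries held far more fungal transcript than control berries, in amounts that differed strongly between replicates. Botrytis genes took 1.35% of the counts in infected replicate 1 (95% exact Clopper-Pearson interval 1.34 to 1.35), 0.136% in replicate 2 (0.135 to 0.137) and 4.12% in replicate 3 (4.12 to 4.13). The mean was 1.87% ± 2.04 (SD, n = 3), and the highest replicate had 30.3 times the share of the lowest. Control berries had 0.00228%, 0.0106% and 0.00247%, with a mean of 0.00512% ± 0.00475 (SD, n = 3). The means differed 365-fold, and the lowest infected library stood 12.8-fold above the highest control library. An exact two-sided permutation test gave p = 0.1, the smallest value that 3 against 3 libraries allow. Leaving out infected replicate 3 lowered the infected mean to 0.741%.

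**Figure D1:**
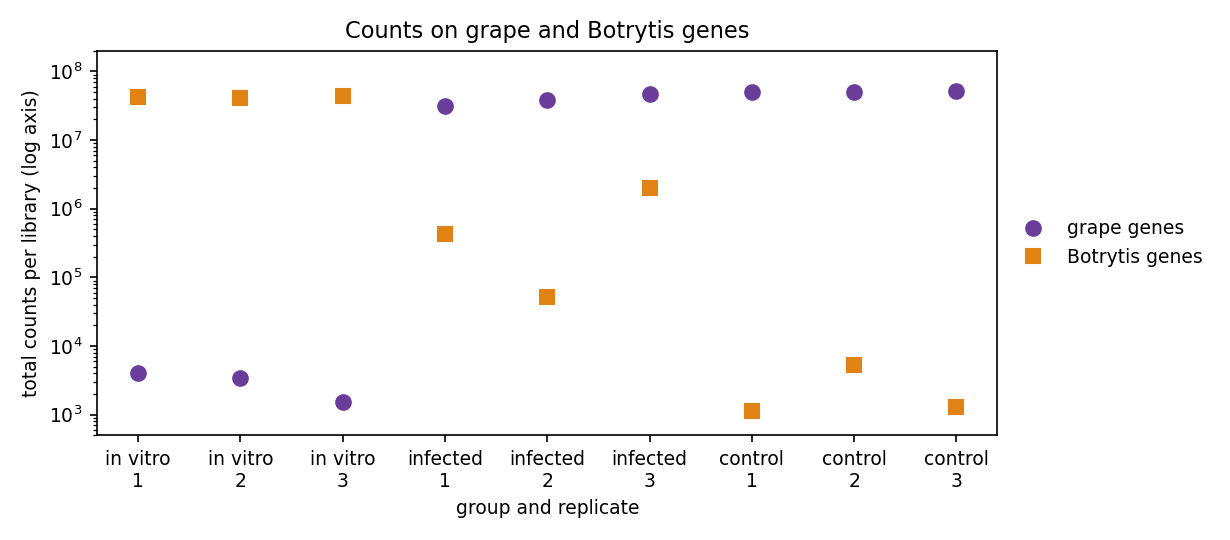
Total counts on grape genes (circles) and Botrytis genes (squares) in each of the 9 libraries, on a log axis. The 3 infected libraries held 432133, 51380 and 2029337 Botrytis counts, against 1129, 5326 and 1286 in the control berries.

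The grape libraries were deep, with 31693512, 37709434 and 47182413 grape counts in infected replicates 1 to 3 and 49431536, 50254209 and 52066545 in the controls. The Botrytis libraries in vitro held 42398996, 40732692 and 43483240 Botrytis counts. Infected berries held 432133, 51380 and 2029337 Botrytis counts in replicates 1, 2 and 3, where 5815, 1135 and 8071 Botrytis genes reached 10 counts. Depth therefore limits what replicate 2 can show for single fungal genes.

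The first comparison asked how the berry transcriptome changed with infection. The grape gene VIT_05s0062g00710 rose from 1.21 ± 0.165 to 17.2 ± 9.14 CPM (SD, n = 3), a log2 fold change of 3.83 (SE 0.38, adjusted p = 0.000108). VIT_03s0063g01560 rose by 3.61 on the log2 scale (SE 0.35, adjusted p = 9.75e-05). VIT_01s0026g02620 fell from 16.9 ± 3.86 to 1.39 ± 0.389 CPM, a log2 fold change of -3.62 (SE 0.23, adjusted p = 2.13e-05). VIT_18s0001g14800 fell by 3.44 on the log2 scale (SE 0.41, adjusted p = 0.000243). These IDs carry no gene name in the sources used here. Each of the 4 kept its call and direction under all 15 alternatives run for it.

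Infection changed a large part of the grape genes by modest amounts. Of 20039 genes tested, 10595 (52.9%) passed, 5320 higher and 5275 lower in infected berries. Among them 1763 rose and 646 fell at least 2-fold, 291 rose and 72 fell at least 4-fold, and 26 rose and 7 fell at least 8-fold. The median absolute log2 change of the called genes was 0.55. The libraries of the groups did not overlap in 12549 genes (62.6%), where chance gives 10%. Of the called genes 50.2% were higher. With library totals in place of TMM this share was 33.8%, since the median log2 change of all genes then shifted by -0.15, so directions of small changes are relative to the scaling.

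**Figure D2:**
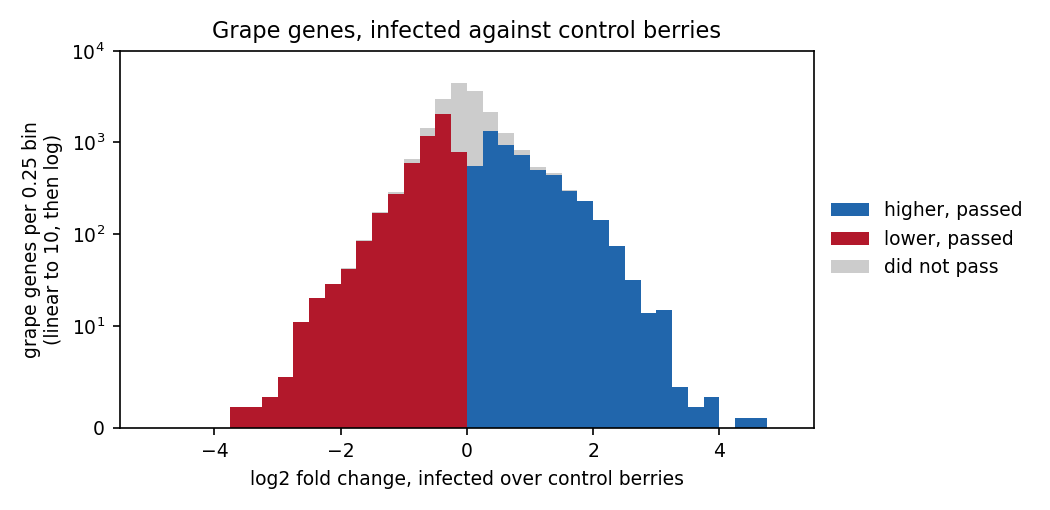
Number of grape genes per bin of log2 fold change, infected over control berries, on an axis that is linear to 10 and then logarithmic. Blue and red mark the 5320 genes called higher and the 5275 called lower, and grey marks genes that did not pass.

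The second comparison asked which Botrytis genes differed between the fungus in berries and in culture. Among the gene lists, 16 of 18 cytosolic ribosomal protein genes and 6 of 8 pectin-degrading genes were higher in berries, and 4 of 5 botrydial and 13 of 15 botcinic acid genes were lower. The test of each of these lists passed with camera and was lost with an estimated correlation (adjusted p = 0.533). Of 10130 Botrytis genes tested, 4107 (40.5%) passed, 1805 higher and 2302 lower in berries. The 2593 tested genes with a symbol, from which the lists were drawn, had 580 higher and 430 lower. Of the 4107 called genes, 1104 rose and 1718 fell at least 2-fold, 422 rose and 842 fell at least 4-fold, and the median absolute log2 change of called genes was 1.36. Among the genes tested, 455 had at least 50 counts in every in vitro library and at most 3 over the infected libraries, against 0 in the other direction. Fitted folds of such genes can exceed what their counts bound, as for Bcdmats2 (fitted log2 -8.42, at least 1.66-fold lower by the floor). The numbers of large falls thus depend in part on depth. The groups did not overlap in 4641 genes (45.8%). Chance gives 10% only for libraries of like depth. The infected libraries held far fewer Botrytis counts, so genes with few counts can separate without a change, and this share has no chance value to be set against.

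The number of Botrytis genes called rested on the deepest infected library. Without infected replicate 3 it fell to 2139 (947 higher, 1192 lower), and limma-trend called 1659. The share of called genes that were higher was 44.0%, against 56.4% with upper-quartile factors and 59.2% with library totals, which shifted the median log2 change of all Botrytis genes by 0.17 and 0.21. No gene called here and in an alternative had opposite directions in them. Infected replicate 2, with the fewest fungal counts, lay nearer the culture than replicate 1 did. Fitted as a mixture of the in vitro profile and that of infected replicate 3, its Botrytis profile took 43.1% from the in vitro profile, against 1.20% in replicate 1.

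Both phytotoxin clusters were lower in berries. Botrydial is a sesquiterpene toxin, and Bcbot2, its sesquiterpene cyclase, fell from 1004 ± 96.7 to 54.9 ± 89.6 CPM (SD, n = 3), a log2 fold change of -6.63 (SE 1.22, adjusted p = 0.00345). Its infected CPM were 4.33, 158 and 1.92 in replicates 1, 2 and 3. The fold is fitted to counts, where deeper libraries weigh more, so it is larger than the ratio of the mean CPM here and for other falling genes that were high in infected replicate 2. Bcbot5 fell by 6.36 (SE 0.94), Bcbot3 by 4.85 (SE 1.11) and Bcbot4 by 3.74 (SE 0.58) on the log2 scale. Bcbot1 had a log2 fold change of -4.29 with an adjusted p of 0.0891. Of 5 botrydial genes tested 0 rose and 4 fell, and 5 fell when adjusted over the list alone or without infected replicate 2. The camera test placed the list lower (adjusted p = 0.0423), and the adjusted p was 0.533 with an estimated correlation. The call was also lost without infected replicate 1 (adjusted p = 0.154) or 3 (0.322) and after subtraction of the control counts (0.0587), at list medians on the log2 CPM scale of -5.08, -4.75 and -8.09, against -5.73 with all libraries and no subtraction.

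The botcinic acid cluster, which makes a polyketide toxin, had 0 genes higher and 13 lower of 15 tested, with 2 not passing. The same 13 was the count adjusted over the list alone. Bcboa3 fell from 610 ± 97.2 to 76.4 ± 86.3 CPM (SD, n = 3), a log2 fold change of -3.79 (SE 0.63, adjusted p = 0.00221). Bcboa10 had 3 counts over the infected libraries and 3697 in vitro, a ratio of 24.4 with a counting interval of 8.36 to 119. The list median was -3.79 and camera gave an adjusted p of 0.00026, or adjusted p = 0.533 with an estimated correlation. The call was lost without infected replicate 3 (adjusted p = 0.1), at a list median on the log2 CPM scale of -3.61, against -3.76 with all libraries. That median moved more, to -2.76 without infected replicate 1 and to -4.57 without replicate 2, where the call held.

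As a share of Botrytis counts, toxin transcripts were highest in infected replicate 2 among the infected libraries. The botrydial genes took 0.688% ± 0.0936 of Botrytis counts in vitro (SD, n = 3) and 0.0731% ± 0.112 in infected berries, where the highest share, 0.202%, was that of replicate 2. The botcinic acid genes took 0.312% ± 0.0173 in vitro and 0.102% ± 0.145 in infected berries, with 0.269% in replicate 2, 0.0132% in replicate 1 and 0.0234% in replicate 3. The few Botrytis counts of the control berries held 0.602% ± 0.0334 botrydial and 0.366% ± 0.0612 botcinic acid transcripts. Without infected replicate 2 the log2 fold change was -8.73 for Bcbot2, -7.62 for Bcbot5, -6.79 for Bcbot3, -4.42 for Bcbot4 and -11.28 for Bcbot1. Without infected replicate 3 Bcbot2 was at -4.84, Bcbot5 at -4.82 and Bcbot4 at -3.15, and Bcbot3 at -3.79 did not pass. Without infected replicate 1 the values were -5.99 for Bcbot2, -4.01 for Bcbot3 and -3.16 for Bcboa3.

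Of 8 pectin-degrading genes tested 6 rose, 0 fell and 2 did not pass, with the same counts when adjusted over the list alone and without infected replicate 2. BcPG3, an endopolygalacturonase, rose from 30.0 ± 11.8 to 313 ± 82.4 CPM (SD, n = 3), a 10.8-fold change (log2 3.43, SE 0.32, adjusted p = 0.000168). Bcpg5, another endopolygalacturonase, rose 43.6-fold (log2 5.45, SE 0.28, adjusted p = 1.46e-05) from 0.489 ± 0.0401 CPM. The list median was 4.34, and camera gave an adjusted p of 0.000111, or adjusted p = 0.533 with an estimated correlation. On the log2 CPM scale the median was 3.57 with all libraries. It was 3.17, 4.34 and 3.38 without infected replicates 1, 2 and 3, with the camera call kept. The pectin genes together took 0.331% ± 0.0255 of Botrytis counts in vitro and 0.423% ± 0.103 in infected berries (SD, n = 3), most of them from Bcpg1, which did not pass (log2 -0.19).

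The cellulose, hemicellulose and cutin list moved both ways. Of 6 genes 3 rose, 2 fell and 1 did not pass, and 4 rose and 2 fell when adjusted over the list alone. The xylanase gene Bcxyn11A rose by 3.39 (SE 0.27), Bccel5A by 2.65 (SE 0.45) and the cutinase gene BccutA by 2.47 (SE 0.32) on the log2 scale. BccutB had a log2 fold change of 1.40 with an adjusted p of 0.0675. Bcara2 fell by 1.51 on the log2 scale (SE 0.24). Bcara1 had 0 counts in the infected libraries and 532 in vitro, which makes it at least 3.52-fold lower, a call lost without infected replicate 3. The median was 1.94 and the mean -0.18, and camera did not pass (adjusted p = 0.314, direction higher). BccutA and Bcara2 did not pass with limma-trend. Only 1 gene fell without any of the in vitro libraries or infected replicate 3. Camera passed without in vitro replicate 2 or 3, where Bcara1 was not tested and the list median on the log2 CPM scale was 2.01 or 2.23.

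Secreted inducers of plant cell death changed in both directions. Bcnep2, a necrosis- and ethylene-inducing protein, rose from 26.5 ± 5.50 to 554 ± 52.9 CPM (SD, n = 3), a 21.2-fold change (log2 4.40, SE 0.23, adjusted p = 1.46e-05). Bccrh1 rose by 2.14 (SE 0.25) and Bcplp1 by 1.22 (SE 0.21) on the log2 scale. Bcspl1, a cerato-platanin, fell by 1.97 on the log2 scale (SE 0.43, adjusted p = 0.00775). Bcssp120, which entered the list by the pattern on its symbol alone, had a log2 fold change of -0.41 with an adjusted p of 0.251. Its function was not checked. Bcnep1 had 1 count in the infected libraries and 125 in vitro, a ratio of 2.48 with a counting interval of 0.437 to 98.7. In total 3 of 6 rose, 1 fell and 2 did not pass, also when adjusted over the list alone, and camera gave an adjusted p of 0.0944 with a median of 0.41, while the share of the list in Botrytis counts was 1.47% ± 0.216 in vitro and 0.619% ± 0.364 in infected berries (SD, n = 3). Without infected replicate 3, Bcplp1 (0.94) and Bcspl1 (-1.70) did not pass, and limma-trend lost the same pair. Without infected replicate 2 Bcspl1 was at -2.62. Camera passed without any of the in vitro libraries, at list medians on the log2 CPM scale from 0.97 to 1.04.

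Of 21 protease genes 8 rose, 3 fell and 10 did not pass, with 9 and 3 when adjusted over the list alone. The aspartic protease gene Bcap4 rose from 35.5 ± 12.3 to 341 ± 119 CPM (SD, n = 3), a 10.4-fold change (log2 3.39, SE 0.32, adjusted p = 0.000168). Bcser2 fell by 0.93 on the log2 scale (SE 0.22) and did not pass after thinning. The median was 0.55 and camera did not pass (adjusted p = 0.0798). Without infected replicate 2, 11 genes rose and 3 fell. Over 11 alternatives the list median on the log2 CPM scale ran from -0.08 to 0.82.

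**Figure D3:**
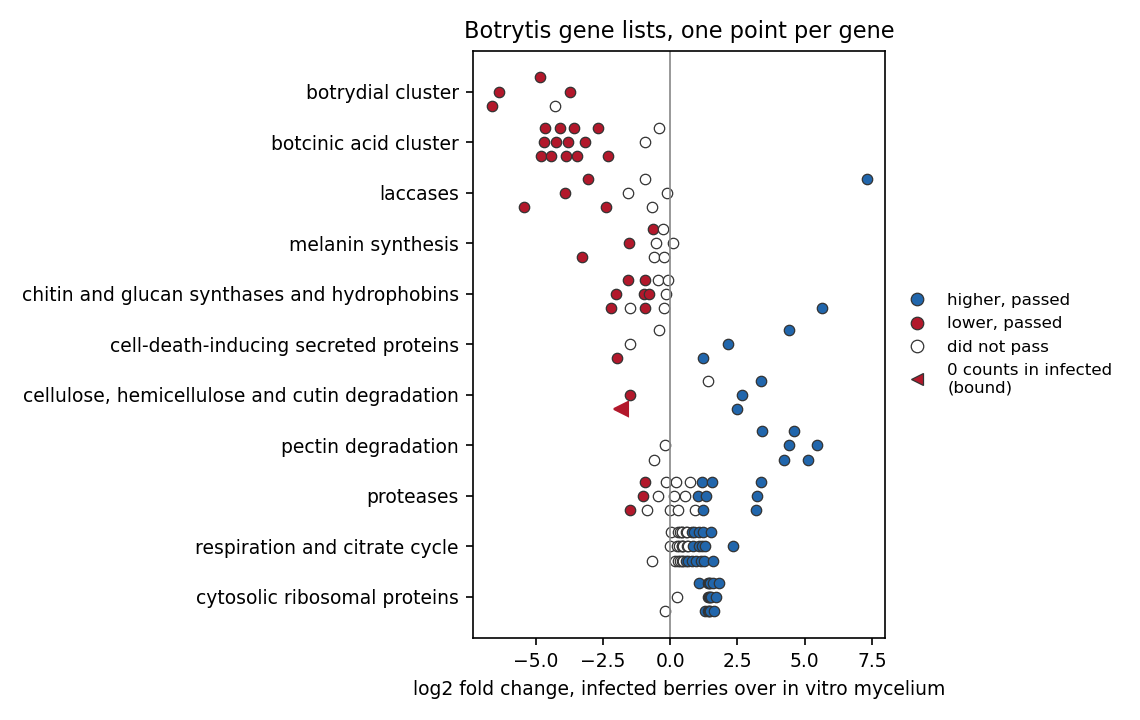
Log2 fold change, infected berries over mycelium in vitro, of each tested gene in 11 Botrytis gene lists. Filled points passed the test, open points did not, the triangle is the bound of Bcara1, at 0 counts in infected berries, and Bcboa10 and Bcnep1, with 3 counts and 1 count there, stand at their fitted values; 16 of 18 ribosomal protein genes lay higher and 13 of 15 botcinic acid genes lower.

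Of 18 cytosolic ribosomal protein genes 16 rose, 0 fell and 2 did not pass, with the same counts when adjusted over the list alone and without infected replicate 2. Bcrpl3 rose from 791 ± 9.54 to 2097 ± 336 CPM (SD, n = 3), a 2.66-fold change (log2 1.41, SE 0.22, adjusted p = 0.00175). Bcrpl25 rose 3.51-fold (log2 1.81, SE 0.26, adjusted p = 0.0011). Also among the named rises, Bcrps12, Bcrps31, Bcrpl29, Bcrps20, Bcrpl32 and Bcrpl5, had log2 fold changes of 1.63, 1.57, 1.51, 1.48, 1.48 and 1.43. The list median was 1.44, and camera gave an adjusted p of 8.13e-13, or adjusted p = 0.533 with an estimated correlation. The ribosomal genes took 0.799% ± 0.0365 of Botrytis counts in vitro and 2.43% ± 0.386 in infected berries (SD, n = 3).

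Among genes with a symbol and at least 50 counts in every infected library, the largest rise was that of Bcilv5, of branched-chain amino acid synthesis, which went from 240 ± 22.0 to 901 ± 191 CPM (SD, n = 3; log2 1.91, SE 0.23, adjusted p = 0.000509). Bcgbl1 and Bchex6 rose by 1.42 (SE 0.23) and 1.40 (SE 0.21) on the log2 scale.

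Of 38 genes of respiration and the citrate cycle 17 rose, 0 fell and 21 did not pass, with 18 rising when adjusted over the list alone. Bcmdh1, malate dehydrogenase, rose from 336 ± 23.3 to 811 ± 60.4 CPM (SD, n = 3; log2 1.28, SE 0.19, adjusted p = 0.00139). Bccit3 had a log2 fold change of 2.32 (SE 0.40, adjusted p = 0.00258), with 113, 0 and 285 counts in infected replicates 1, 2 and 3, and limma-trend gave it the opposite sign without a call. The list median was 0.61, and camera gave an adjusted p of 5.21e-10, or adjusted p = 0.533 with an estimated correlation. The count of rises was 11 without in vitro replicate 1, 10 without in vitro replicate 3 and 25 without infected replicate 2, and 30 with upper-quartile factors or library totals.

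Both tested genes of the glyoxylate cycle and fatty acid oxidation rose, also when adjusted over the list alone. These were Bcicl1, isocitrate lyase (log2 1.08, SE 0.21, adjusted p = 0.00453), and Bcpot1 (log2 2.10, SE 0.40, adjusted p = 0.00415). A list of 2 genes was too short for camera, and with limma-trend Bcicl1 did not pass and Bcpot1 changed sign without a call.

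Of 31 proteasome genes 7 rose, 1 fell and 23 did not pass, with 5 and 1 when adjusted over the list alone. The gene that fell was Bcrpn4, whose yeast counterpart activates proteasome genes, from 1129 ± 565 to 212 ± 148 CPM (SD, n = 3; log2 -2.65, SE 0.53, adjusted p = 0.00506). The list median was 0.36, and camera gave an adjusted p of 0.00146, or adjusted p = 0.533 with an estimated correlation. Fry did not pass (adjusted p = 0.331). With all libraries the 7 rises were about the same share as the 580 higher among 2593 tested genes with a symbol. The list thus held no clear excess of called genes. Over 11 alternatives its median on the log2 CPM scale ran from 0.002 to 0.37. Rises numbered 2 without in vitro replicate 1, 3 without in vitro replicate 2 or 3 or without infected replicate 3, 4 without infected replicate 1 and 16 without infected replicate 2. Bcrpn4 did not pass without infected replicate 3, at -2.46.

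Among laccases a single gene rose against 4 that fell. Bclcc2, a laccase tied to the oxidation of resveratrol, rose from 16.3 ± 2.80 to 2531 ± 2124 CPM (SD, n = 3), a 158-fold change (log2 7.31, SE 1.07, adjusted p = 0.00123). Its infected counts were 1884, 7 and 7087 in replicates 1, 2 and 3. Bclcc8 fell from 154 ± 18.0 to 12.8 ± 16.4 CPM (log2 -5.42, SE 0.43, adjusted p = 9.07e-05), and was at -4.32 without infected replicate 3. Of 9 laccase genes 4 did not pass, and 1 rose and 5 fell when adjusted over the list alone. The median was -1.57 and camera did not pass (adjusted p = 0.203).

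**Figure D4:**
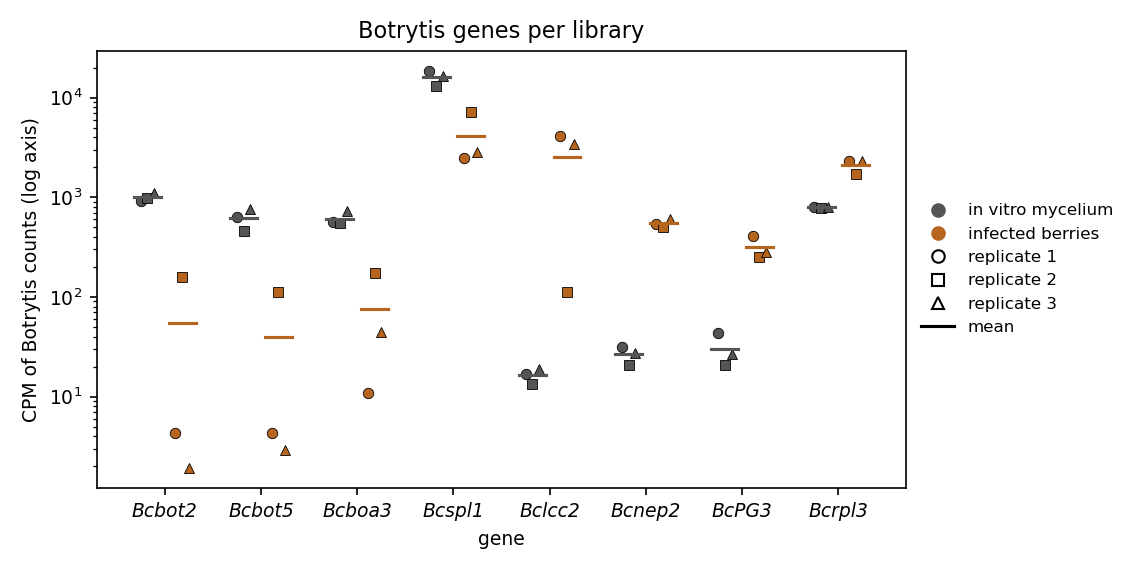
CPM of Botrytis counts on a log axis for 8 named genes, with a symbol per replicate and a line at the mean of each group. Bclcc2 reached a mean of 2531 CPM in infected berries but lay lowest in replicate 2, the replicate with the highest values of Bcbot2, Bcbot5, Bcboa3 and Bcspl1 among the infected libraries.

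Other synthesis genes of secondary metabolites moved both ways. Of 39 polyketide synthases, peptide synthetases and terpene cyclases 8 rose, 6 fell and 25 did not pass, also when adjusted over the list alone. These shares were near those of the 2593 tested genes with a symbol, 580 higher and 430 lower. Bcpks13, a polyketide synthase of melanin synthesis, fell from 622 ± 66.4 to 77.7 ± 33.3 CPM (SD, n = 3; log2 -3.28, SE 0.32, adjusted p = 0.000203). Bcpks7 fell by 5.62 on the log2 scale (SE 0.85). The terpene cyclase gene Bcstc4 was at 0 in the infected libraries with 1071 counts in vitro, at least 7.08-fold lower, and Bcdmats2 was at least 1.66-fold lower with 251 counts in vitro. The median was 0.37, the mean -0.20 and the test direction higher (camera adjusted p = 0.261). Without infected replicate 2 Bcpks7 was at -8.00, and without replicate 3 at -3.66. Bcpks7 and Bcdmats2 did not pass with DESeq2, Bcpks7 did not with limma-trend, and Bcstc4 and Bcdmats2 did not without infected replicate 3, nor Bcdmats2 without replicate 1 or with upper-quartile factors or library totals. Falls numbered 3 without in vitro replicate 1 or 2 and 2 without infected replicate 3, and rises 5 without in vitro replicate 1 or 3 or infected replicate 3.

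Of 8 melanin genes, which include Bcpks13, 0 rose, 3 fell and 5 did not pass, also when adjusted over the list alone (median -0.56, camera adjusted p = 0.211), and 1 fell without infected replicate 1. Further genes at 0 counts in all infected libraries were Bcaba2, of abscisic acid synthesis, at least 6.62-fold lower with 1002 counts in vitro, and Bcrgs5, at least 3.85-fold lower with 582. Both calls were lost without infected replicate 3. Bcpie2 fell by 5.32 on the log2 scale (SE 1.20), with -6.87 without infected replicate 2, -4.43 without infected replicate 1 or in vitro replicate 3, and no call at -4.24 without infected replicate 3.

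Genes that make or remove reactive oxygen species split, with 7 of 34 higher, 10 lower and 17 not passing, also when adjusted over the list alone. BcnoxB, a catalytic subunit of NADPH oxidase, fell from 821 ± 149 to 274 ± 170 CPM (SD, n = 3; log2 -1.78, SE 0.43, adjusted p = 0.0118). Bccat8 rose by 2.51 on the log2 scale (SE 0.45). The median was -0.17 while camera pointed higher (adjusted p = 0.709), and the median turned to 0.01 with upper-quartile factors and 0.06 with library totals. Without infected replicate 3 only 3 rose and 2 fell, with BcnoxB at -1.31 and Bccat8 at 2.10 not passing, and BcnoxB was at -1.79 without a call without infected replicate 1. Falls numbered 5 without any other library except infected replicate 2, rises 4 and 3 without in vitro replicates 2 and 3, and limma-trend called neither gene.

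Of 15 ABC and MFS transporter genes 2 rose, 6 fell and 7 did not pass, also when adjusted over the list alone (median -0.70, camera adjusted p = 0.284). The Bcmfs1 gene with the ID Bcin01g09910 fell by 3.69 on the log2 scale (SE 0.67). It was at -4.45 without infected replicate 2, and at -2.71 without a call without replicate 3; DESeq2 and limma-trend did not call it. Falls numbered 3 and rises 0 without infected replicate 3, and rises 0 without in vitro replicate 1 or infected replicate 1 and 1 without in vitro replicate 2 or 3.

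Of 5 genes of sugar transport and use 2 rose, 0 fell and 3 did not pass, also when adjusted over the list alone. The hexose transporter gene Bchxt15 rose from 3.23 ± 0.244 to 59.7 ± 56.3 CPM (SD, n = 3; log2 4.74, SE 0.36, adjusted p = 7.85e-05), with 0 counts in infected replicate 2. The glucokinase gene Bcglk rose by 0.70 on the log2 scale (SE 0.22). Bchxk, BcFrt1 and Bchxt19 had log2 fold changes of -0.12, -0.37 and -0.43 with adjusted p of 0.69, 0.2 and 0.541. The median of -0.12 turned to 0.09 with upper-quartile factors and 0.14 with library totals, the mean was 0.90, and camera did not pass (adjusted p = 0.744, direction higher). Bchxt15 was at 4.03 without infected replicate 3 and was not called with limma-trend. Bcglk lost its call without any library except infected replicate 2, at values from 0.52 to 0.81, which left 1 rise.

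Of 22 regulators of light response, clock and development 2 rose, 9 fell and 11 did not pass, also when adjusted over the list alone. The clock gene Bcfrq1 fell from 288 ± 19.5 to 115 ± 79.4 CPM (SD, n = 3; log2 -1.75, SE 0.33, adjusted p = 0.00367). Bcltf6, named as a light-responsive transcription factor, rose by 3.01 on the log2 scale (SE 0.32). The median was -0.55 and camera did not pass (adjusted p = 0.203). Without infected replicate 3 there were 4 falls and Bcfrq1, at -1.65, did not pass, and limma-trend called neither gene. The culture was grown at 22 °C, while berries had a daily light and temperature cycle.

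Of 24 genes for signalling kinases and G proteins 0 rose, 7 fell and 17 did not pass, also when adjusted over the list alone (median -0.32, camera adjusted p = 0.211). Bcg3, a G protein alpha subunit, fell from 206 ± 18.1 to 62.9 ± 13.7 CPM (SD, n = 3; log2 -1.60, SE 0.17, adjusted p = 0.000303). The osmosensing histidine kinase gene Bos1 fell by 0.80 (SE 0.23), a call lost without any library except infected replicate 2, at values from -0.82 to -0.63, and under upper-quartile factors and library totals.

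Of 13 genes for chitin and glucan synthases and hydrophobins 1 rose, 7 fell and 5 did not pass, also when adjusted over the list alone (median -0.92, camera adjusted p = 0.0944). The hydrophobin gene Bhp2 was the gene that rose, 49.7-fold (log2 5.64, SE 0.28, adjusted p = 1.46e-05), from 1.85 ± 0.241 to 71.5 ± 48.3 CPM (SD, n = 3). The chitin synthase gene BcCHSV fell by 0.92 (SE 0.25), a call lost without any library except infected replicate 2, at values from -0.95 to -0.77. Camera passed without any of the in vitro libraries, at list medians on the log2 CPM scale from -0.81 to -0.76.

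Of 13 genes of ergosterol synthesis 0 rose, 5 fell and 8 did not pass, also when adjusted over the list alone (median -0.38, camera adjusted p = 0.203). Bcerg12 fell from 152 ± 19.5 to 55.0 ± 8.97 CPM (SD, n = 3; log2 -1.52, SE 0.19, adjusted p = 0.00051), and Bcerg10 fell by 1.38 (SE 0.30). Without infected replicate 3 Bcerg10, at -1.20, did not pass and 2 genes fell, and 3 fell without infected replicate 1 or in vitro replicate 3. With library totals 1 gene rose.

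Among 4 heat shock protein genes Bchsp104, a disaggregase, fell from 1722 ± 1359 to 188 ± 126 CPM (SD, n = 3; log2 -3.44, SE 0.66, adjusted p = 0.00419), and was at -2.53 without in vitro replicate 3. Bchsp78 fell by 1.48 (SE 0.37) and Bchsp60 rose by 0.79 (SE 0.20), while Bchsp10 had a log2 fold change of 0.38 (adjusted p = 0.291). The counts, 1 higher, 2 lower and 1 not passing, were the same when adjusted over the list alone, with a median of -0.55 and a camera adjusted p of 0.788. Bchsp78 lost its call without infected replicate 1 (-1.46) or 3 (-1.55). Bchsp60 lost it without infected replicate 1 (0.51) or in vitro replicate 2 (0.75) or 3 (0.75), and Bchsp10 passed without infected replicate 2 (0.49).

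Of 14 genes for histones and replication 6 rose, 0 fell and 8 did not pass, also when adjusted over the list alone (median 0.20, camera adjusted p = 0.191). Bcpol30 rose by 0.47 (SE 0.15) and Bcpol4 by 1.17 (SE 0.37) on the log2 scale. At most 2 genes rose when any library except infected replicate 2 was left out, and 0 without infected replicate 3. Where its call was lost, Bcpol30 lay between 0.33 and 0.52 and Bcpol4 between 0.97 and 1.35.

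None of the 5 reference genes passed, with edgeR or adjusted over the list alone, although 2 had an unadjusted p under 0.05, DESeq2 called 4 and limma-trend 0. Bcef1a, BctubB, BcactA, Bctub4 and BctubA had log2 fold changes of 0.61, 0.41, 0.30, 0.05 and -0.60. Without infected replicate 2, Bcef1a (0.71), BctubB (0.46) and BcactA (0.37) passed as higher and BctubA (-0.46) as lower. With upper-quartile factors or library totals 3 passed as higher. The median was 0.30 and camera gave an adjusted p of 0.261.

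Of the 22 lists that camera tested, it called 4 higher and 2 lower relative to the other genes. With an estimated correlation 0 passed, and 0 had an unadjusted camera p under 0.05. The lowest was 0.0543, for pectin degradation, and the adjustment gave many lists the same 0.533. For the cell-death list the estimated correlation was 0.0164, near the preset 0.01, yet the unadjusted camera p went from 0.0386 to 0.111. Calls lost under this setting thus need not reflect correlation between genes. Fry called 15. Of 62 named Botrytis genes called, 57 passed with DESeq2, 43 with limma-trend and 41 without infected replicate 3.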

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

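The tests on the control berries and the count of genes in infected replicate 2 above every source were chosen after the result was seen; the other tests of replicate 2 were fixed before their results were seen.

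Botrytis counts appeared in the control berries, which received no fungus: 1129 in replicate 1, 5326 in replicate 2 and 1286 in replicate 3. Fungal counts relative to grape counts differed 4.64-fold between control libraries with nearly equal grape totals. This argues against reads of grape counted on fungal genes as the only source in replicate 2. Replicates 1 and 3 differed 1.08-fold, so their totals alone leave such reads open. Fitted as a mixture of the in vitro profile and that of infected replicate 3, the counts took 69.8% (95% interval 63.3 to 76.2), 91.0% (88.4 to 93.5) and 79.7% (73.9 to 85.1) from the in vitro profile. In control replicates 1 and 3, the 98 genes at least 32 times higher in vitro gave 72.6% (50.6 to 101) and 87% (64.1 to 115), on 36 and 49 counts. Grape reads would not follow the fungal profile, so these shares argue against them as the only source there, though not as a part. Reads or RNA carried over from the in vitro libraries are therefore a candidate source. Fungus growing in control berries as it does in culture would give the same profile, so at a highest share of 91% these sources cannot be told apart.

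Grape counts appeared in the in vitro mycelium, which was grown without grape: 4053, 3403 and 1527 in replicates 1, 2 and 3. The cause was not tested.

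In the same mixture infected replicate 2 took 43.1% (95% interval 42.1 to 44.1) of its Botrytis profile from the in vitro profile, against 1.20% in replicate 1. Counting noise is argued against, since replicate 1 thinned to the same total reached at most 1.64% in 100 draws. Carried-over in vitro reads stay open, as the share was 33.5% (31.1 to 36.1) from genes at least 32 times higher in vitro than in replicate 3 and 46.4% (44.5 to 48.3) from genes 2 to 8 times higher, within the 1.5 times set beforehand for these 2 groups; genes 8 to 32 times higher gave 30.3% (28.2 to 32.6), more than 1.5 times below the 46.4%, so the shares were not uniform. They would need 22145 such counts, where the control library with most held 4847, and are argued against as the only difference of that library, since 77 of its genes lay above every in vitro library and infected replicate 3, against 8 to 27 in thinned replicate 1. Another stage of infection in that replicate stays open and cannot be told apart from carry-over, because a single library shows the pattern.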

How the results depend on the processing

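The subtraction of control counts and the list counts without infected replicate 2 were chosen after the data had been seen. Grape calls were stable in number except under a threshold of at least 2-fold, which by construction left 2409 genes (1763 higher, 646 lower). Leaving out each library in turn gave 8918 to 10176 grape genes (4554 to 5204 higher, 4364 to 4972 lower), and 2139 to 4786 Botrytis genes (947 to 2202 higher, 1192 to 2584 lower), the lowest without infected replicate 3, the library with most fungal counts. For Botrytis, limma-trend called 1659 genes (552 higher, 1107 lower), a replicate block called 1107 genes higher, and an adjusted p under 0.01 left 2432 (1065 higher, 1367 lower). Thinning every library to the smallest Botrytis total, with 1133 genes tested in place of 10130, called 417 (204 higher, 213 lower), and the 2-fold threshold left 1104 higher. The mean fungal share ranged from 0.741% to 2.73% as single libraries were left out. Fry pointed lower, where camera pointed higher without passing, for the cellulose, hemicellulose and cutin list (median 0.70 on the log2 CPM scale) and the reactive oxygen list (median -0.46). Camera compares a list with the other genes and fry does not. The reactive oxygen median lay below 0 but above the median of all Botrytis genes on that scale, -0.61, where the directions can differ. For the cellulose, hemicellulose and cutin list the cause was not tested. Limma-trend gave Bccit3 -1.09, Bcpot1 -0.56 and Bcpol4 -0.98, each at 0 counts in infected replicate 2. It weighs all libraries equally on the log2 CPM scale, so the shallow replicate 2 counts as much as the others. Its median log2 change of all Botrytis genes was -0.61, against -0.07 with edgeR. No test of the cause was run. Of the results for lists 212 were the same, 17 gained and 11 lost a call; for named Botrytis genes 1101 were the same, 22 gained and 89 lost a call; all 60 for named grape genes were the same. With a replicate block 9216 grape genes passed, and the protease list passed in Botrytis (adjusted p = 0.0462, over its alternatives 0.0462 to 0.533). Same-numbered libraries showed no pairing: their residual correlations ran from -0.244 to -0.0631 in grape and from -0.0511 to -0.00723 in Botrytis. Depth limits the Botrytis genes that infected replicate 2 can show, with 1135 reaching 10 counts there. In simulation 26.4% of 2-fold Botrytis changes were recovered, with far fewer genes changed than were called in the real data.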

Other observations

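Gene families not listed beforehand were tested after the data had been seen, by grouping Botrytis genes by symbol; the other tests in this part were fixed before their results were seen. Among 94 families of at least 5 tested genes, 188 one-sided Fisher's exact tests were run for an excess of called genes against the 2593 tested genes with a symbol, of which 580 were higher and 430 lower. These tests take genes as independent, and families outside the gene lists had no test that allows for correlation between genes. Of 20 genes for large-subunit proteins of the mitochondrial ribosome 16 were higher in berries (median log2 0.93, adjusted p = 6.05e-06), among them Bcmrpl9 at 1.19 (SE 0.18). This count was 10 without infected replicate 3 and 8 with limma-trend. All 5 lysine synthesis genes were higher (median 1.55, adjusted p = 0.0148), with Bclys12 at 2.95 (SE 0.19) and Bclys4 at 2.24 (SE 0.15), and all 5 were called without each single library, although the family test gave 0.0676 with upper-quartile factors and 0.0614 with library totals. Of 15 nucleolar protein genes 9 were higher (median 0.76, adjusted p = 0.0419, or 0.0564 with DESeq2 size factors), with Bcnop58 at 1.28 (SE 0.15), which did not pass after thinning (0.79). The families of small- and large-subunit cytosolic ribosomal proteins (7 of 7 and 8 of 9) and of botcinic acid genes (13 of 15), already listed above, also passed, in tests that take genes as independent; the camera tests of both lists were lost with an estimated correlation (adjusted p = 0.533). These genes were chosen after their values were seen.

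Genes named for their dependence on calcineurin, a calcium-dependent phosphatase, were mostly lower in berries: 9 of 10 (median -1.63, Fisher's exact test adjusted p = 4.73e-05). That test takes genes as independent, which genes sharing a regulator need not be. CND1 fell from 7827 ± 1499 to 1109 ± 546 CPM (SD, n = 3; log2 -2.85, SE 0.41) and CND17 by 2.15 (SE 0.25) on the log2 scale. The count was 5 without infected replicate 1, 6 without infected replicate 3 and 10 without infected replicate 2. Of 8 genes with the phosphate-regulation symbol 6 were lower and 1 higher (median -0.86, adjusted p = 0.0131), with Bcpho81 at -1.64 (SE 0.29), or -0.85 without a call after thinning, and 3 genes were lower without infected replicate 3 or with limma-trend. Without the minimum of 50 counts, the rule for named genes also takes in rising genes with few counts in infected replicate 2. Bcgas5 rose from 11.7 ± 2.49 to 1827 ± 959 CPM (log2 7.31, SE 0.54, or 6.55 after thinning), and the pectin methylesterase gene Bcpme2 rose from 7.34 ± 0.676 to 152 ± 64.7 CPM (log2 4.59, SE 0.22). These genes, too, were chosen after their values were seen.

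A hypothesis was that Botrytis genes changed in berries lie side by side, as clusters of secondary metabolism do. Neighbouring genes called in the same direction formed 1147 pairs, against a mean of 842 and a highest of 926 in 1000 random gene orders (permutation p = 0.001, the smallest they can give). Without the botrydial and botcinic acid genes there were 1132 pairs against a highest of 921. Runs of at least 5 genes numbered 10 higher and 17 lower; the longest lower run held 13 botcinic acid genes, and the longest higher run held 10 genes, of which the last, Bcpks5, was at 0.28 without a call when infected replicate 3 was left out, against 2.08, and was also lost with DESeq2 and limma-trend. The values are consistent with changed genes being grouped along chromosomes, though neighbours may also share reads or regulation unrelated to infection.

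A second hypothesis was that the fungal load of a berry library sets the size of the grape response. Over the 2146 grape genes called at least 2-fold without infected replicate 2, the median signed log2 shift from the control mean was 1.53 in replicate 2, 1.35 in replicate 1 and 1.37 in replicate 3. The library with the fewest fungal counts thus had no smaller response, which argues against the hypothesis for these libraries.

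The 10 splits of 6 libraries into 3 against 3 are too few for a share under 0.05. The real split gave 10595 grape genes and 4107 Botrytis genes with edgeR, 1 split in each case, and the highest of the other splits gave 0 and 0. At an unadjusted p under 0.05 the real splits gave 11762 and 5062 genes, and the highest other splits 484 and 438. Every other split mixed both groups in each arm, so the group difference entered its spread. Their counts thus do not measure a rate of false calls. No other tool was run on the splits.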
